A study of Homo sapiens with 2 samples.

How the data were processed

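PAR-CLIP libraries of Flag/HA-tagged ZC3H7A and Flag/HA-tagged ZC3H7B from HEK293 cells were analysed, 1 library for each protein, named replicate 1 in the labels. Per the labels' protocols, expression was induced for 24 h with 1 µg/mL doxycycline, RNA was labelled for 16 h with 100 µM 4-thiouridine, cells were irradiated at 365 nm, complexes were immunoprecipitated and treated with RNase T1, and libraries were read as 50 bp single ends. Groups were taken from the sample titles. RNase T1 cuts after G, size selection of gel slices limits fragment length, and no molecular identifier is described, so reads of 1 library can be PCR copies of each other.

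The authors deposited 1 table per library with 1 row per gene. Per the submitters' processing notes, cutadapt, Bowtie and STAR 2.5.2a were used with genome build hg19, without their roles or settings. The cluster caller and its thresholds are not given in the sources used here. The deposited counts are, per the file headers, the number of clusters, the reads summed over clusters, the distinct reads summed over clusters and the clusters in the 5' UTR, intron, exon, 3' UTR, start codon and stop codon. Reads outside clusters do not enter these counts. The deposited fraction is the median over clusters of the fraction of reads with a T-to-C conversion, and its sum over clusters is given beside it. A deposited log10 score of conversion specificity was read, as its values fit it, as the log10 of T-to-C over other conversions, and it was not used for a comparison. The exon column was used as coding sequence, because a row with 1 cluster had that cluster in it exactly when its class was coding, in 2200 of 2200 and 1762 of 1762 such rows. In rows with 1 cluster, the T-to-C fraction times the reads was a whole number within 1e-06 in 2200 of 2200 and 1760 of 1762. Regions are given as numbers of clusters and not as reads, so region shares are shares of clusters. No named region was given for 4.87% of clusters in the ZC3H7A library and 5.21% in the ZC3H7B library.

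Rows that name a class of repeats, tRNAs or other small RNAs and no single gene were left out of the gene comparisons. There were 282 such rows of 8486 in the ZC3H7A table, with 1.57% of its reads, and 407 of 9566 in the ZC3H7B table, with 1.51%. The lowest read sum of a listed gene was 5 in the ZC3H7A library and 4 in the ZC3H7B library. Gene symbols were matched to a RefSeq gene table of assembly GRCh38.p14, which served for names and biotypes only, and no coordinates were used. It matched 7881 of 8204 and 8736 of 9159 symbols.

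With 1 library per protein no test of a difference between the proteins, standard error or p-value was computed, and percentiles among random lists and intervals over genes describe these libraries. The planned count of shared genes expected among the genes listed in either table cannot lie below the count found, so it was not used. Shares are given with exact Clopper-Pearson 95% intervals. The log2 ratio of a gene is its reads in the ZC3H7B library over those in the ZC3H7A library, for genes listed in both with at least 20 reads summed, scaled so that the median of these genes is 0. A gene was counted as higher in a library where the whole exact interval lay beyond 2-fold. Intervals and limits cover counting error only, with each count taken as independent. PCR copies make intervals on reads too narrow even for that error. The lengths covered by clusters were not used, so a sum over clusters also moves with how many were called, and mean reads per cluster and numbers of clusters were used as alternatives. Gene lists were fixed before the data were examined. A list with at least 5 genes is described by its median and by the percentile of that median among 10000 random lists of the same size, matched on the decile of mean reads. The coding share of a list is the median over genes with at least 3 clusters. Its random lists were drawn from all such genes, coding or not. The mean difference within genes has a 95% interval from 2000 bootstrap draws over genes.

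The genes named were chosen by a rule written before the data were examined. They are ZC3H7A and ZC3H7B, the 10 genes with the most reads in each library, the 10 highest and 10 lowest ratios among genes with at least 100 reads summed, the 5 genes with the most reads listed in a single library, and 2 to 4 members with the most reads of each list. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. TMM factors came from edgeR 4.0.16 in R 4.3.3, which served for scaling and for no test.

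The ratio step was tested on simulated counts for 7155 genes with the means and totals of these libraries. Of 100 genes set 4-fold higher in the ZC3H7B library, 97 were called, and of 99 set 4-fold lower, 84 were called (84.8%). None of 6956 unchanged genes was called, and 95.7% of their intervals held 0. Simulated reads were independent draws without PCR copies, so these rates do not cover the duplication of the real libraries. Of 100 random lists without a change, 9 lay outside the 2.5th to 97.5th percentile of matched lists. The alternatives were other minimum reads, other scales, thinned libraries, clusters, distinct reads or mean reads per cluster in place of reads, missing genes kept at 0, exonic classes alone, and other weights of genes. A planned comparison with codon content was not run, because coding sequences were not used here.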

Results

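Photoactivatable-ribonucleoside-enhanced crosslinking and immunoprecipitation (PAR-CLIP) was used to record where ZC3H7A and ZC3H7B, a pair of CCCH zinc finger proteins, contacted RNA in HEK293 cells, a line derived from human embryonic kidney. Each protein carried a Flag/HA tag and was induced with doxycycline. Crosslinks at 4-thiouridine are read as T-to-C conversions, and overlapping reads are grouped into clusters. There was 1 library for each protein and no control library, so no value has a replicate check and no difference between the proteins was tested. The title of the series names codon-dependent regulation of translation and stability, and the comparisons below ask which transcripts and which transcript regions each protein was recovered on. The ZC3H7A library held 3779662 reads in 51808 clusters on 8204 genes, made of 300342 distinct reads. The ZC3H7B library held 2409465 reads in 99805 clusters on 9159 genes, made of 1212989 distinct reads. Each distinct read was therefore counted 12.6 times on average in the ZC3H7A library and 1.99 times in the ZC3H7B library. Intervals are exact 95% intervals for counting error only, with each count taken as independent. PCR copies are not independent molecules, so intervals on reads are too narrow even for that error.

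The transcripts of the tagged proteins were compared before the other genes, because an induced transgene adds its own messenger RNA. ZC3H7A was the gene with the most reads in its own library, with 82704 reads or 2.19% of the total (2.17 to 2.20%). With ZC3H7B tagged it held 158 reads, or 0.00656% (0.00557 to 0.00766%), a share 334-fold lower. ZC3H7B held 3768 reads in its own library, or 0.156% (0.151 to 0.161%), and ranked 36 by reads. In the ZC3H7A library it held 1362 reads, or 0.0360% (0.0341 to 0.0380%), a share 4.34-fold lower. Of the 28 ZC3H7A clusters in its own library, 14 lay in coding sequence, 2 at the start codon, 2 in the 3' UTR and 10 in no named region. Of the 35 ZC3H7B clusters in its own library, 17 lay in coding sequence and 9 in the 3' UTR. Both genes therefore had more reads in the library labelled with their own protein. Counted in distinct reads, the shares differed 144-fold for ZC3H7A and 3.28-fold for ZC3H7B. Counted in clusters and set against the median gene, ZC3H7B lay slightly on the other side, at a log2 ratio of -0.19.

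Among the 10 genes with the most reads in each library, 5 were common to both. These were CBX5, which encodes the heterochromatin protein HP1 alpha, ERC1, a vesicle scaffold, KLHL15, an adaptor of a ubiquitin ligase, NUFIP2, an RNA-binding protein, and ZNF711, a zinc finger transcription factor. The other leading genes of the ZC3H7A library were ZC3H7A itself, HNRNPA2B1 (25355 reads), the linker histone gene HIST1H1C (18305 reads), NCL, which encodes nucleolin (17637 reads), and the transcription factor SP1 (15405 reads). Those of the ZC3H7B library were SCD, a fatty acid desaturase (8908 reads), MAP1B, a microtubule-associated protein (8292 reads), SON, a splicing cofactor (7308 reads), CCND2, which encodes cyclin D2 (6991 reads), and NUCKS1, a chromatin-associated protein (6787 reads). ERC1 led the ZC3H7B library with 29520 reads, 1.23% of its total. CBX5 had 80 of 85 clusters in its 3' UTR in the ZC3H7A library and 77 of 83 in the ZC3H7B library, whereas MAP1B had 56 of 84 and 59 of 95 in coding sequence. The 10 leading genes took 7.04% of the reads of the ZC3H7A library and 4.08% of those of the ZC3H7B library. The median gene carried 4 clusters and 135.5 reads in the ZC3H7A library, and 7 clusters and 82 reads in the ZC3H7B library. Which library had more genes depended on the minimum, with 8024 for ZC3H7A and 8082 for ZC3H7B at 10 reads per gene, and 6054 and 5526 at 50.

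Most genes with clusters were shared by the libraries. Of the 8204 genes with clusters in the ZC3H7A library, 7218 (88.0%) also had clusters in the ZC3H7B library, where they made up 78.8% of the 9159 listed. A further 986 genes were listed only for ZC3H7A and 1941 only for ZC3H7B, and a gene missing from a table has no called cluster, which is not a count of 0 reads. Sharing followed read number. In the ZC3H7A library 67.6% of the lowest decile of genes by reads (median 14 reads) and 99.9% of the highest decile (median 1801 reads) were listed for ZC3H7B. For ZC3H7B these values were 38.3% (median 6 reads) and 100%. Among annotated coding genes, 7585 were listed for ZC3H7A and 8429 for ZC3H7B, with 6861 in both. Independent lists of these sizes drawn from all 20056 coding genes would share 3188, which is 2.15-fold fewer. Not all of these genes need be expressed, and expression was not analysed here.

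The genes with the most reads among those listed for a single library were of mixed kinds. For ZC3H7A they were the histone H3 gene HIST1H3D (1644 reads), the 5S ribosomal RNA pseudogene RNA5SP382 (997 reads), CFL1, which encodes cofilin (638 reads), the antisense transcript HOXB-AS3 (536 reads) and RP11-844G16.1 (502 reads). The median T-to-C fraction of clusters was 0.63 on HIST1H3D, 0.10 on RNA5SP382 and 0.12 on RP11-844G16.1, and 1.00 on CFL1 and HOXB-AS3. For ZC3H7B they were the ribosomal protein pseudogene RPS2P5 (515 reads), GSE1 (418 reads), the transcription factor CSRNP2 (403 reads), KCTD1 (382 reads) and the protein kinase SIK2 (341 reads). GSE1 had 18 of 19 clusters in the 3' UTR, CSRNP2 14 of 17 and SIK2 21 of 26, whereas KCTD1 had 25 of 26 in introns. Histone genes, pseudogenes and antisense genes share sequence or position with other genes, so their reads are uncertain between copies.

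The libraries differed in where on the transcript the clusters lay. Coding sequence held 42.7% of clusters (42.2 to 43.1%) in the ZC3H7A library and 29.6% (29.3 to 29.8%) in the ZC3H7B library. The 3' UTR held 39.8% (39.4 to 40.2%) and 55.8% (55.5 to 56.1%). The 5' UTR held 3.61% (3.45 to 3.77%) and 0.772% (0.718 to 0.828%), a 4.68-fold higher share in the ZC3H7A library, and clusters at start codons were 2.22-fold more frequent there (1.43% against 0.645%). Stop codons held 1.46% and 1.85%, and introns 6.18% (5.98 to 6.39%) and 6.13% (5.98 to 6.28%), intervals that overlap. By gene, 69.97% of the genes listed for ZC3H7A and 65.99% of those for ZC3H7B had a cluster in coding sequence, and 58.9% and 74.7% had a cluster in the 3' UTR.

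**Figure D1:**
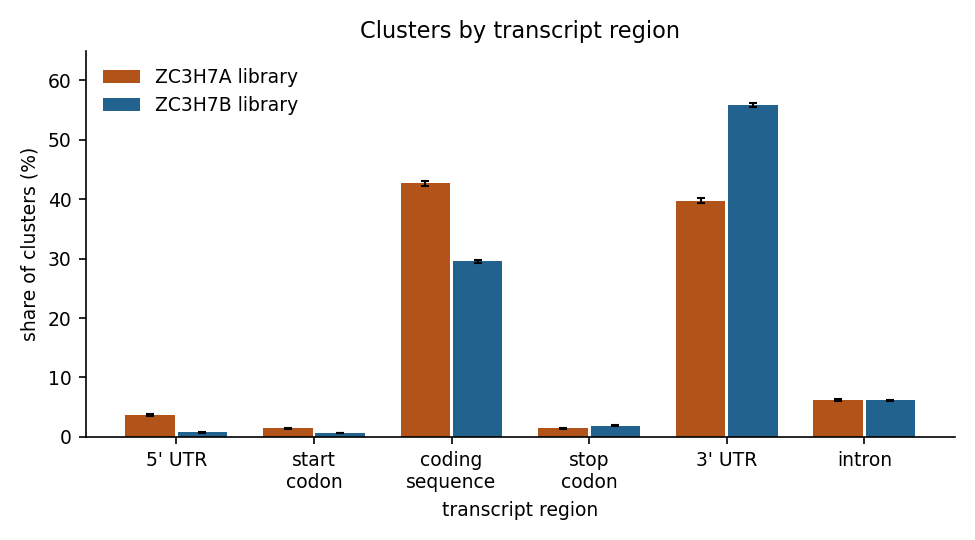
Share of clusters (%, vertical axis) in each transcript region (horizontal axis) for the ZC3H7A library (brown, 51808 clusters) and the ZC3H7B library (blue, 99805 clusters), with exact 95% counting intervals as error bars. The 3' UTR bar is higher for ZC3H7B (55.8% against 39.8%) and the coding sequence bar is higher for ZC3H7A (42.7% against 29.6%).

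The same difference was present within genes. Over the 5988 genes with at least 20 reads in both libraries, the coding share of a gene was higher in the ZC3H7A library for 3617 genes, higher in the ZC3H7B library for 1415 and equal for 956. The median difference, ZC3H7B minus ZC3H7A, was -8.33 percentage points and the mean was -11.4 points. The 3' UTR share was higher in the ZC3H7B library for 3761 genes and in the ZC3H7A library for 1099, with a median difference of 10.0 points. HNRNPU, an RNA-binding protein of the nucleus, had 22 of 36 clusters in coding sequence in the ZC3H7A library and 10 of 42 in the ZC3H7B library. SSR1, a subunit of the translocon-associated complex, had 8 of 15 and 7 of 35. The condensin subunit gene SMC2 had 22 of 27 and 20 of 36. The centromere protein gene CENPF did not differ in this way, with 54 of 61 and 70 of 79 clusters in coding sequence. KLHL15, with 12 of 65 and 15 of 46, and PKM, with 9 of 17 and 12 of 15, went the other way.

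T-to-C conversion was high in the called clusters on genes of both libraries. The thresholds of the cluster caller are not given, and any threshold on conversion would raise these values. The share of reads with a conversion, averaged over clusters within a gene and weighted by reads, was 92.0% in the ZC3H7A library and 89.2% in the ZC3H7B library. The median gene stood at 97.4% and 91.1%. The mean share over clusters was 100%, within a fraction of 1e-09, for 3128 of 8204 genes (38.1%) and 1491 of 9159 genes (16.3%). The median gene had 13 distinct reads in the ZC3H7A library and 47 in the ZC3H7B library, and 100% is easier to reach with few reads. A mean share under 50% was found on 52 genes of the ZC3H7A library and 11 of the ZC3H7B library.

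Reads per gene were correlated between the libraries. Across the 7218 genes listed in both, Pearson's r on log2 reads was 0.70 and Spearman's rho 0.709, and genes are not independent replicates. Log2 ratios of ZC3H7B over ZC3H7A were scaled so that the median of 7168 genes with at least 20 reads summed was 0. The whole interval lay above 2-fold for 1306 genes (higher in the ZC3H7B library) and below for 1293 (higher in the ZC3H7A library), and 4569 did neither. Within the ZC3H7B library the 1306 genes had 66.1% of their clusters in 3' UTRs and the 1293 genes 41.9%, and within the ZC3H7A library these shares were 57.3% and 28.0%. Coding sequence held 23.6% and 38.8% within the ZC3H7B library, and 30.4% and 50.2% within the ZC3H7A library. These ratios describe 1 pair of libraries, not the conditions, and reads are summed over clusters called separately in each. The counts were 522 and 724 with distinct reads in place of reads (515 and 702 of them the same genes), 443 and 333 with mean reads per cluster, 23 and 16 with clusters, and 2102 and 2039 with missing genes kept at 0. Of 62 named genes with an interval beyond 2-fold, 14 no longer had one with distinct reads, 26 with mean reads per cluster and 54 with clusters.

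**Figure D2:**
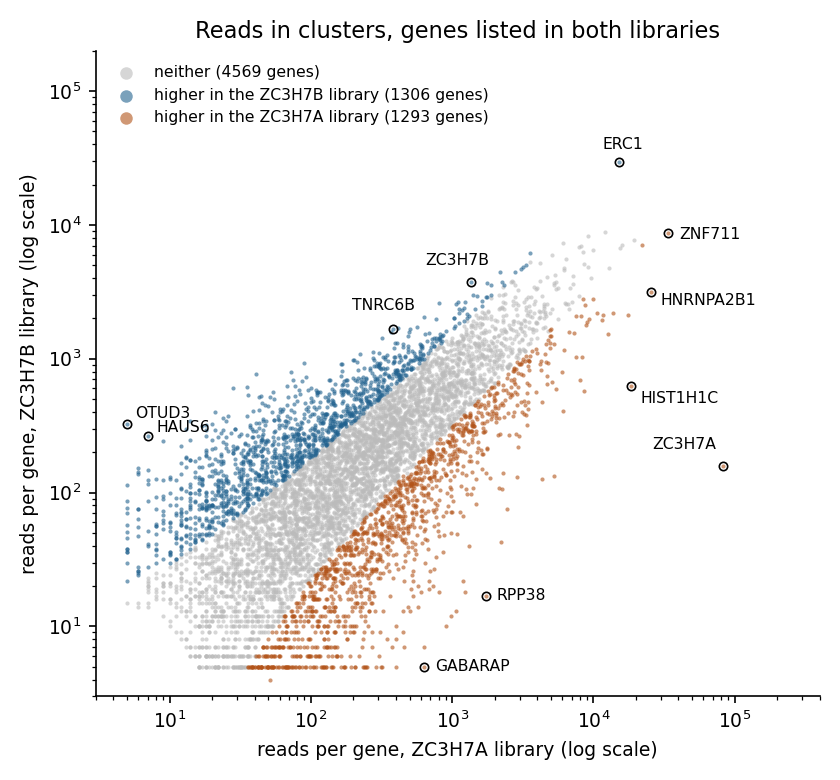
Reads in clusters per gene in the ZC3H7A library (horizontal axis, log scale) and the ZC3H7B library (vertical axis, log scale), 1 point for each of 7168 genes, coloured by whether the counting interval of the ratio lies beyond 2-fold. The 1306 genes higher in the ZC3H7B library lie above the grey band and the 1293 higher in the ZC3H7A library below it, with ZC3H7A itself at 82704 and 158 reads.

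Among 5855 genes with at least 100 reads summed, ZC3H7A itself was farthest towards the ZC3H7A library, with a log2 ratio of -8.54 (-8.77 to -8.31). After it came GABARAP, an autophagy protein, at -6.50 (-8.13 to -5.27), and RPP38, a subunit of ribonuclease P, at -6.18 (-6.96 to -5.49). CPNE1, a phospholipid-binding copine, stood at -6.02 (-7.08 to -5.13) and KDELR1, a retention receptor of the endoplasmic reticulum, at -6.01 (-7.33 to -4.96). The histone genes H2AFX and H1FX stood at -5.86 and -5.85, LGALS3BP, a secreted galectin-binding protein, at -5.82, CENPW, a kinetochore protein, at -5.61 and ATP5G2, a subunit of ATP synthase, at -5.53. RPP38 had 8 clusters in the ZC3H7A library, 7 of them in coding sequence, and 1 cluster of 17 reads in the ZC3H7B library. In the ZC3H7B library 6 of the 10 genes had 1 cluster. GABARAP and LGALS3BP had 5 reads there, KDELR1 and ATP5G2 7 and CPNE1 10, near the lowest read sum of a listed gene (4). GABARAP, LGALS3BP and ATP5G2 had 3 distinct reads each. All 10 genes had intervals beyond 2-fold with distinct reads too. By mean reads per cluster this did not hold for all of them. ATP5G2, then at -1.97, and KDELR1 lost their intervals beyond 2-fold.

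At the other end, OTUD3, a deubiquitinase, had the highest log2 ratio, 6.52 (5.28 to 8.15), with 5 reads in 1 cluster in the ZC3H7A library and 325 reads in 22 clusters in the ZC3H7B library. HAUS6, a subunit of the augmin complex, stood at 5.72 (4.66 to 7.05), RCAN1, a regulator of calcineurin, at 5.24 (4.29 to 6.39), and LSG1, a ribosome maturation GTPase, at 5.16 (4.00 to 6.62). TMEM246 stood at 5.11, the zinc finger gene ZSCAN22 at 5.06, NIN, which encodes the centrosomal protein ninein, at 5.02, the mitotic kinase gene NEK9 and ZNF618 at 5.0 and C6orf89 at 4.92. In the ZC3H7B library 143 of the 166 clusters of these genes lay in 3' UTRs. In the ZC3H7A library each of the 10 had 1 cluster, with 5 to 28 reads made of 2 distinct reads. With distinct reads the log2 ratio was lower than with reads for each of them except C6orf89 (5.44). It was 4.67 for OTUD3, 2.75 for HAUS6 and 3.09 for NEK9. In this count 9 of the 10 kept an interval beyond 2-fold, and HAUS6 did not. These genes had 7 (HAUS6) to 31 (C6orf89) clusters in the ZC3H7B library, so mean reads per cluster gave smaller ratios for all 10. By that measure C6orf89, ZNF618 and TMEM246 did not keep an interval beyond 2-fold.

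Of 23 gene lists fixed before the data were examined, 17 had at least 5 genes to compare, and 7 had a median ratio below the 2.5th percentile of 10000 random lists matched on reads, all towards the ZC3H7A library. None lay above the range of the random lists. Replication-dependent histone genes stood farthest out, with a median log2 ratio of -3.05 (0th percentile, random lists -0.75 to 0.62). Of 22 compared, 21 were higher in the ZC3H7A library and 0 in the ZC3H7B library (19 and 0 with distinct reads). HIST1H1C stood at -4.38 (-4.49 to -4.26), HIST1H3B at -4.61 (-4.88 to -4.35) and HIST1H4C at -1.63 (-1.73 to -1.53). With distinct reads HIST1H1C stood at -3.46 (-3.70 to -3.23), and by mean reads per cluster HIST1H4C stood at -0.07. By mean reads per cluster the list stood at -1.29, still below the random range. In clusters in place of reads HIST1H3B stood at 0.07, with 2 clusters in the ZC3H7A library and 4 in the ZC3H7B library. Histone genes share sequence, so reads are uncertain between copies.

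Both lists of ribosomal protein genes had medians below the random range, though many members were called in neither direction. Cytosolic ribosomal protein genes had a median log2 ratio of -1.91 (0th percentile), with 36 of 65 higher in the ZC3H7A library and 2 in the ZC3H7B library. RPL35A stood at -2.56 (-2.72 to -2.41) and RPS4X at -1.91 (-2.05 to -1.78), while RPL15 stood at 0.18 (0.11 to 0.25) and RPL5 at 0.49 (0.40 to 0.57). With distinct reads RPL15 stood at -0.17 (-0.40 to 0.05) and RPL5 at -0.08 (-0.37 to 0.21), so neither kept its direction. Mitochondrial ribosomal protein genes had a median of -1.42 (0th percentile), with 32 of 61 higher in the ZC3H7A library and 1 in the ZC3H7B library. MRPL19 stood at -1.80 (-1.90 to -1.70) and MRPS30 at -1.42 (-1.54 to -1.30), and MRPL42 stood at -0.62 (-0.76 to -0.48). With distinct reads MRPS30 stood at -0.48 (-0.77 to -0.18), no longer beyond 2-fold. In this count 33 of 65 cytosolic and 23 of 61 mitochondrial genes were higher in the ZC3H7A library, and 1 of each list in the ZC3H7B library. With mean reads per cluster the median of the cytosolic list was -0.58, still below the range of random lists, and that of the mitochondrial list was -0.18, within it. Pseudogenes of ribosomal proteins can hold reads of their parent genes.

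Genes of the proteasome, the respiratory chain, the cytoskeleton with glycolysis, and the chaperones made up the rest of the 7 lists. Respiratory chain genes encoded in the nucleus had a median log2 ratio of -1.26 (0th percentile), with 31 of 63 higher in the ZC3H7A library and 1 in the ZC3H7B library. ATP5B, a subunit of ATP synthase, stood at -1.26 (-1.37 to -1.15), NDUFAF4, an assembly factor of complex I, at -1.66 (-1.82 to -1.50), and UQCRB, a subunit of complex III, at -1.50 (-1.66 to -1.35), or 0.07 when clusters took the place of reads. Proteasome genes had a median of -1.22 (0.04th percentile), with 13 of 27 higher in the ZC3H7A library and 1 in the ZC3H7B library. PSMD12 stood at -1.70 (-1.81 to -1.60) and PSMA4 at -0.30 (-0.41 to -0.18). Cytoskeleton and glycolysis genes had a median of -1.83 (0th percentile), with 9 of 13 higher in the ZC3H7A library and 1 in the ZC3H7B library. The glycolytic enzyme genes ENO1, LDHB and PKM stood at -2.68 (-2.82 to -2.55), -2.08 (-2.15 to -2.01) and -2.60 (-2.82 to -2.38), and VIM, which encodes vimentin, at -1.28 (-1.42 to -1.14). Chaperone genes had a median of -1.02 (0.595th percentile), with 9 of 21 higher in the ZC3H7A library and 1 in the ZC3H7B library, and HSP90AA1 stood at -2.16 (-2.22 to -2.09), HSP90AB1 at -1.81 (-1.88 to -1.73) and HSPD1 at -2.42 (-2.53 to -2.32). Counted in distinct reads, the intervals of ATP5B (-1.12), NDUFAF4 (-0.98), UQCRB (-1.19) and PSMD12 (-1.09) no longer lay beyond 2-fold. The numbers higher in the ZC3H7A library were then 18 of 63 (respiratory chain), 8 of 27 (proteasome), 10 of 13 (cytoskeleton) and 6 of 21 (chaperones). Those higher in the ZC3H7B library were 0, 0, 1 and 1. With mean reads per cluster the cytoskeleton list (-0.18) and the chaperone list (-0.10) lay within the random range, the respiratory chain (-0.48) and proteasome (-0.46) lists stayed below it with smaller medians, and VIM stood at 0.28. Among random lists matched also on the 3' UTR share of clusters, the proteasome list (3.45th percentile) and the chaperone list (13.1th percentile) lay within the range.

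**Figure D3:**
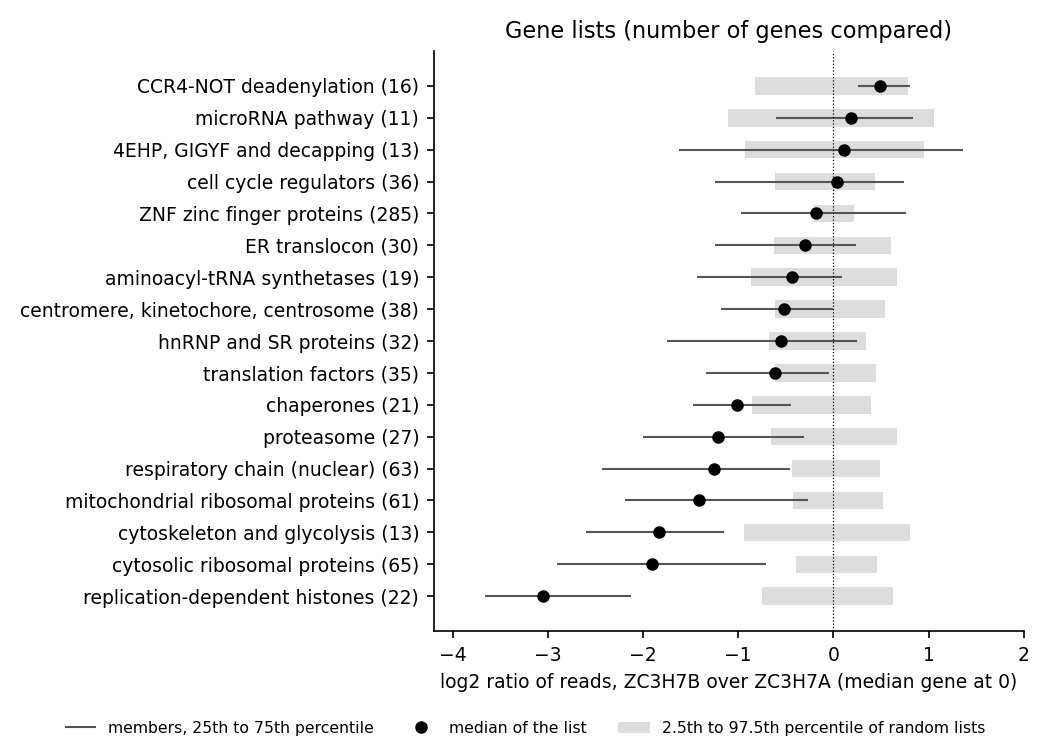
Median log2 ratio of reads, ZC3H7B over ZC3H7A (horizontal axis), for 17 gene lists (vertical axis, number of genes compared in parentheses), with the middle 50% of members as lines and the central 95% of 10000 matched random lists as grey bars. The 7 lists left of their grey bars run from chaperones (-1.02) to replication-dependent histones (-3.05), and 0 lists lie to the right.

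The remaining 10 lists lay within the range of random lists in the main setting, so no direction was read from them. Translation factor genes had a median log2 ratio of -0.61 (2.73th percentile), with 10 of 35 higher in the ZC3H7A library and 3 in the ZC3H7B library. It fell below the random range with distinct reads (-0.68), with clusters (-0.55) and with missing genes kept (-0.75). GSPT1, a release factor, stood at -1.54 (-1.62 to -1.45), or -1.03 and not wholly beyond 2-fold with distinct reads, and EIF4G2, an initiation factor, at 0.24 (0.17 to 0.31). With distinct reads EIF4G2 stood at -0.04 (-0.23 to 0.15). EEF2, an elongation factor, stood at -1.09 (-1.17 to -1.01), and at 0.47 by mean reads per cluster. Splicing regulators of the hnRNP and SR families had a median of -0.55 (6.97th percentile), with 9 of 32 higher in the ZC3H7A library and 1 in the ZC3H7B library. HNRNPA2B1 stood at -2.53 (-2.58 to -2.47), HNRNPU at -1.73 (-1.80 to -1.66), SRSF1 at 0.16 (0.10 to 0.21) and SON at 0.76 (0.72 to 0.81). With distinct reads SRSF1 turned to -0.39 (-0.55 to -0.23), and SON stood at 0.56 (0.43 to 0.69). Centromere, kinetochore and centrosome genes had a median of -0.52 (4.84th percentile), with 6 of 38 higher in the ZC3H7A library and 3 in the ZC3H7B library. SMC2 stood at -1.55 (-1.69 to -1.42) and CENPF at -0.57 (-0.65 to -0.50). By mean reads per cluster this list stood at -0.48, below the random range. In distinct reads 7 of 35 translation factor, 7 of 32 splicing and 2 of 38 centromere genes were higher in the ZC3H7A library. Those higher in the ZC3H7B library were 0, 1 and 1.

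Aminoacyl-tRNA synthetase genes had a median of -0.43 (17.1th percentile), with 6 of 19 higher in the ZC3H7A library and 0 in the ZC3H7B library. The tyrosyl and seryl enzymes YARS and SARS stood at -1.95 (-2.07 to -1.83) and -1.77 (-1.91 to -1.63), and NARS stood at -0.32 (-0.41 to -0.24). Genes of the translocon of the endoplasmic reticulum had a median of -0.30 (17.2th percentile), with 7 of 30 higher in the ZC3H7A library and 2 in the ZC3H7B library, and SEC62 stood at -1.48 (-1.62 to -1.34) and CANX, which encodes calnexin, at 0.29 (0.21 to 0.36). In clusters in place of reads the translocon list stood at -0.51, below the random range. ZNF zinc finger genes had a median of -0.19 (3.78th percentile), with 49 of 285 higher in the ZC3H7A library and 34 in the ZC3H7B library. ZNF711 stood at -1.48 (-1.51 to -1.44), but at 0.21 by mean reads per cluster, ZNF529 at -1.77 (-1.84 to -1.70) and ZNF146 at 0.36 (0.30 to 0.42). Cell cycle genes had a median of 0.03 (67.6th percentile), with 11 of 36 higher in the ZC3H7A library and 6 in the ZC3H7B library. CCNB1, which encodes cyclin B1, stood at -2.37 (-2.46 to -2.27), CDK1 at -1.46 (-1.53 to -1.39), and CCND2 at 0.26 (0.22 to 0.31). CCND2 stood at -0.07 (-0.19 to 0.06) with distinct reads, and CDK1 at -0.11 by mean reads per cluster. With distinct reads neither SEC62 (-0.84) nor CDK1 (-1.07) kept an interval beyond 2-fold. In this count 2 of 19 synthetase, 4 of 30 translocon, 30 of 285 ZNF and 5 of 36 cell cycle genes were higher in the ZC3H7A library. Those higher in the ZC3H7B library were 0, 0, 10 and 2.

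The lists closest to messenger RNA repression and decay also lay within the range of random lists. Genes of the CCR4-NOT complex and other deadenylation factors had a median log2 ratio of 0.49 (89.0th percentile), with 3 of 16 higher in the ZC3H7B library and 0 in the ZC3H7A library. CNOT1, the scaffold of the complex, stood at 0.70 (0.60 to 0.79). Genes of the 4EHP, GIGYF and decapping list had a median of 0.11 (56.3th percentile), with 5 of 13 higher in the ZC3H7B library and 4 in the ZC3H7A library. TNRC6B, a silencing factor of the microRNA pathway, stood at 2.62 (2.46 to 2.79), and it had 88 clusters in the ZC3H7B library, 85 of them in the 3' UTR, against 11 in the ZC3H7A library. DCP1A, a decapping factor, stood at 2.09 (1.90 to 2.29), and DCP2, the decapping enzyme, at -0.64 (-0.73 to -0.55). By mean reads per cluster DCP1A kept an interval beyond 2-fold and TNRC6B did not. MicroRNA pathway genes had a median of 0.18 (62.4th percentile), with 2 of 11 higher in the ZC3H7B library and 1 in the ZC3H7A library. AGO1, an Argonaute protein, stood at 1.25 (1.05 to 1.44), or 1.06 and not wholly beyond 2-fold with distinct reads, AGO2 at 0.28 (0.07 to 0.50) and LIN28B at -0.29 (-0.42 to -0.17). By mean reads per cluster AGO1 stood at 0.32, also not beyond 2-fold. In distinct reads 2 of 16 deadenylation, 3 of 13 4EHP list and 1 of 11 microRNA pathway genes were higher in the ZC3H7B library. Those higher in the ZC3H7A library were 0, 1 and 1.

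Long noncoding RNAs were too few for a list value. TUG1, a nuclear long noncoding RNA, stood at a log2 ratio of 1.80 (1.63 to 1.98), with 7 clusters in the ZC3H7A library and 37 in the ZC3H7B library. By mean reads per cluster its interval no longer lay beyond 2-fold. MALAT1 had 16 reads in the ZC3H7A library and no called cluster in the ZC3H7B library. The snoRNA host genes SNHG7 and ZFAS1 stood at -0.90 (-1.07 to -0.74) and -0.94 (-1.17 to -0.72). No gene of the mitochondrially encoded list, the list of small structured RNA genes or the list of blood and immune markers was listed in either table under its gene symbol.

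The position of clusters differed between gene lists as well as between libraries. With the clusters of a list pooled, the 3' UTR share was higher in the ZC3H7B library and the coding share higher in the ZC3H7A library in all 18 lists with at least 20 clusters in each, with separate intervals in 10 and 9 of them. As a median over genes the coding share was higher in the ZC3H7A library in all lists described below except the proteasome and cytoskeleton lists. Among genes with at least 3 clusters, the median coding share lay above the central 95% of random lists matched on reads for 8 of 17 lists in the ZC3H7A library and 12 of 17 in the ZC3H7B library. The random lists also held noncoding genes, which lower the random range and so favour lists of coding genes. How much of these results this accounts for was not tested. Centromere, kinetochore and centrosome genes had a median of 80% in the ZC3H7A library and 66.7% in the ZC3H7B library (100th percentile in both). For aminoacyl-tRNA synthetase genes it was 75.7% (99.96th percentile) and 70.6% (100th), for chaperone genes 75% and 58.9% (100th in both), and for replication-dependent histone genes 66.7% (99.2th) and 60% (99.4th). Proteasome genes had 62.3% (98.1th percentile) and 62.5% (100th), hnRNP and SR genes 60% (98.8th) and 43.7% (99.96th), cell cycle genes 60% (98.6th) and 40% (99.7th), and mitochondrial ribosomal protein genes 57.1% (97.95th) and 46.4% (99.8th).

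Several lists lay outside the random range in a single library in the main setting, and no difference between the libraries was tested for them. In the ZC3H7B library the respiratory chain (45.5%, 99.8th percentile), cytoskeleton (59.8%, 99.9th), translation factor (40%, 99.4th) and ZNF lists (32.7%, 99.7th) lay above the random range. In the ZC3H7A library these stood at 57.8% (97.3th percentile), 56.7% (89.1th), 55% (94.0th) and 50.0% (92.5th). There the ZNF and translation factor lists lay above the range with at least 50 reads per gene and among exonic classes, and the respiratory chain list among exonic classes (97.54th). Cytosolic ribosomal protein genes were the exception, with a coding share of 31.0% in the ZC3H7A library, at the 1.87th percentile, and 29.2% (75.3th) in the ZC3H7B library. Translocon genes stood at 60% (96.0th percentile) and 39.6% (97.4th), the 4EHP list at 35.2% (24.8th) and 17.5% (22.4th, or 8.33% and the 2.70th with at least 50 reads per gene), the CCR4-NOT list at 42.7% (49.9th) and 21.8% (39.5th), and microRNA pathway genes at 44.4% (52.2th) and 41.7% (92.97th). Transcripts with short 3' UTRs have little room for 3' UTR clusters, and the lengths of coding sequence and 3' UTR were not used here. The setting with exonic classes alone left out introns, unassigned clusters and genes without an exonic cluster. In the ZC3H7A library the coding share of the histone, hnRNP and cell cycle lists (94.7th, 96.0th and 93.7th percentiles) then lay within the random range. So did that of the cytosolic ribosomal protein list (48.1th) and, in the ZC3H7B library, that of the histone list (96.4th). With at least 50 reads per gene both ribosomal protein lists in the ZC3H7A library (8.70th and 97.48th) and the respiratory chain list in the ZC3H7B library (33.3%, 85.7th) came within it. Among exonic classes the cytosolic ribosomal protein list lay above it in the ZC3H7B library (50.0%, 99.7th).

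**Figure D4:**
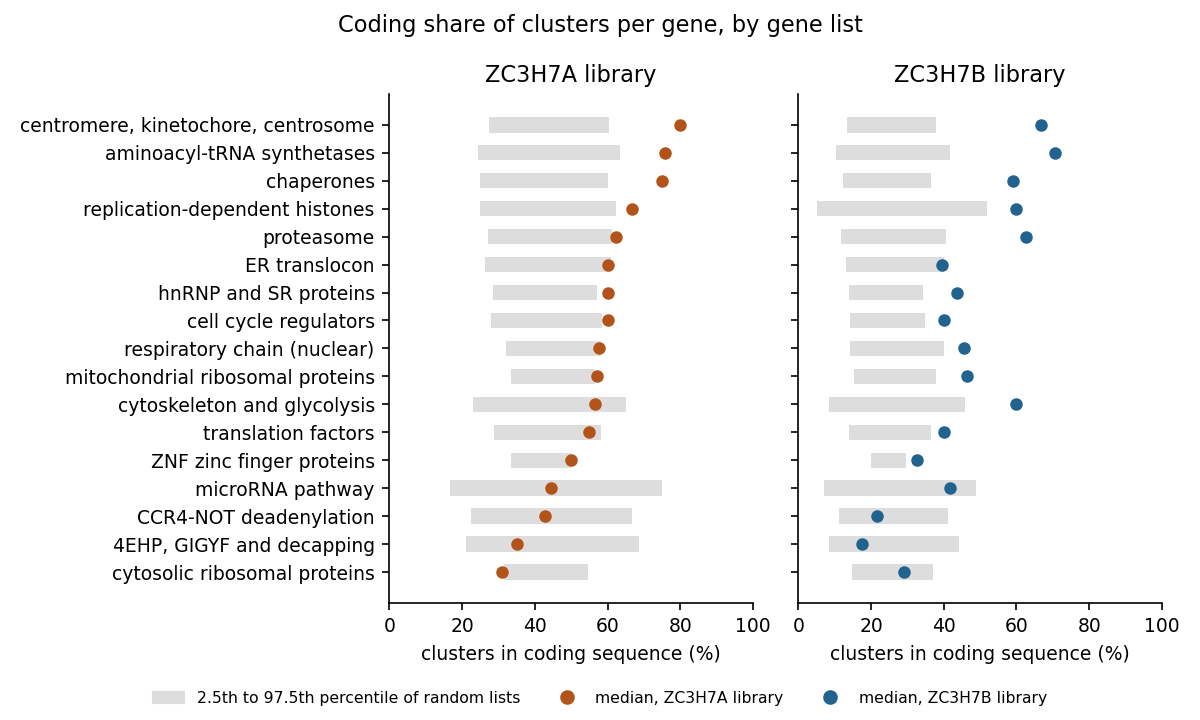
Median over genes of the share of clusters in coding sequence (%, horizontal axes) for 17 gene lists (vertical axis) in the ZC3H7A library (left, brown) and the ZC3H7B library (right, blue), with the central 95% of random lists matched on reads as grey bars. Centromere, kinetochore and centrosome genes lie farthest right in the ZC3H7A library (80%) and aminoacyl-tRNA synthetase genes in the ZC3H7B library (70.6%).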

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

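The tests in this part were chosen after the results were seen. The tables also hold signal outside the gene comparisons, on entries that name a class of RNA and no single gene. Each class named here exceeded the 3 distinct reads that a count of 0 allows, and there was no control library to set it against. Entries for tRNAs held 480 distinct reads in the ZC3H7A library and 109 in the ZC3H7B library. Entries for 7SL, 7SK, 5S and Y RNAs held 319 and 97. Repeat families held 3769 and 19367 distinct reads, a share 0.787 times as high in the ZC3H7A library (0.759 to 0.815).

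The share of tRNA entries was higher in the ZC3H7A library. PCR duplication in that library does not account for it, since the share counted in distinct reads was 17.8-fold higher (14.4 to 22.1, counting error only), against 8.99-fold (8.32 to 9.73) in reads. The share of the other small structured RNAs was 13.3-fold higher (10.6 to 16.9), an interval that overlaps that of the tRNAs. Most of it lay on 7SL (181 and 55 distinct reads) and 7SK (107, with no entry for ZC3H7B). The 5S entry held 20 and 25 distinct reads and the Y RNA HY1 4 and 8. Since the ZC3H7B library held more distinct reads on genes (1212989 against 300342), the shares of 5S and HY1 were also higher in the ZC3H7A library. Of the other Y RNAs, HY4 was listed only for ZC3H7A (7 distinct reads) and HY3 only for ZC3H7B (9). A candidate explanation is a higher recovery of small structured RNAs in the ZC3H7A library. It rests mostly on 7SL and 7SK, and the 5S and Y RNA entries held few distinct reads. The protein itself stays open and untested, because each protein has 1 library. The entry for arginine tRNA of codon AGA held 135 of the 480 distinct tRNA reads in the ZC3H7A library and 60 of 109 in the ZC3H7B library, against 56.0% and 58.1% of tRNA reads, and near-identical tRNA genes cannot be separated by these entries.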

How the results depend on the processing

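The settings with distinct reads, mean reads per cluster, means over clusters, genes weighted by reads, matching on the 3' UTR share, thinned distinct reads, annotated coding genes alone and at least 5 clusters in both libraries were chosen after the data were seen; the others before the data were examined. No paired analysis was possible because each group has 1 library. The comparison with codon content and its alternatives were not run, and no read-based region share could be computed. The shallower tables limit genes with few reads, since a gene below the unknown threshold of the cluster caller is missing and not at 0. The cause of the changes below was not tested except where a setting by itself leaves fewer genes or counts. Scaling by total reads put the median gene at 0.16 and TMM put it at -0.04 (log2); a constant leaves the percentiles of lists unchanged, but with total reads 5 of 62 called named ratios lost their call, and the share of called genes higher in the ZC3H7B library went from 50.3% to 57.8% and 48.4%. Of the 62 named ratios with an interval beyond 2-fold, 14 no longer had one with distinct reads, 26 with mean reads per cluster and 54 with clusters.

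With at least 50 reads per gene 6054 genes were listed for ZC3H7A and 5526 for ZC3H7B, the reverse order of the main counts (8204 and 9159), while with at least 10 reads the order was kept (8024 and 8082). Thinned to the reads of the ZC3H7B library and with at least 10 reads, the ZC3H7A library kept 7739 genes, below 8082. Thinned to the distinct reads of the ZC3H7A library, the ZC3H7B library kept 7867, below 8204. In all, 637 genes were shared among the top 1000 by reads and 627 among the top 1000 by clusters, shorter lists by construction. Among exonic classes alone the coding, 3' UTR and 5' UTR shares were 48.0%, 44.7% and 4.06% for ZC3H7A and 33.3%, 63.0% and 0.870% for ZC3H7B. As means over genes, 3' UTR, 5' UTR and intron shares were 33.9%, 4.17% and 7.12% for ZC3H7A, and coding and 3' UTR shares 30.4% and 52.0% for ZC3H7B. With genes weighted by reads, 3' UTR and intron shares were 38.1% and 5.12% for ZC3H7A, and coding, 3' UTR, 5' UTR and intron shares 28.1%, 56.6%, 0.997% and 5.83% for ZC3H7B. The order of the libraries in coding, 3' UTR and 5' UTR share was the same in each of these settings. T-to-C conversion was 97.4% and 91.1% at the median gene, 91.9% and 89.1% with at least 50 reads and 93.4% and 90.1% as means over clusters. Spearman's rho was 0.664 with at least 50 reads summed. The median coding difference within genes was -10.0 points with at least 50 reads, -9.21 for exonic classes and -10.4 with at least 5 clusters.

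Genes higher in the ZC3H7B and the ZC3H7A library numbered 2102 and 2039 with missing genes kept at 0, 23 and 16 with clusters (fewer counts by construction), 522 and 724 with distinct reads, and 443 and 333 with mean reads per cluster. Among the 62 named ratios beyond 2-fold, the log2 ratio turned with clusters for HIST1H3B (0.074), UQCRB (0.074) and ZC3H7B (-0.19). With mean reads per cluster it turned for EEF2 (0.47), VIM (0.28) and ZNF711 (0.21). Named ratios not beyond 2-fold could turn too, as for ATP5A1 (-0.62, or 0.26 with mean reads per cluster). Translation factors fell below the random range with missing genes kept at a prior of 0.5 reads (-0.75), clusters (-0.55) and distinct reads (-0.68), the translocon list with clusters (-0.51) and the centromere list with mean reads per cluster (-0.48). The proteasome (-1.22) and chaperone (-1.02) lists came within the range when matched on the 3' UTR share, and the mitochondrial ribosomal (-0.18), chaperone (-0.10) and cytoskeleton (-0.18) lists with mean reads per cluster.

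For coding shares in the ZC3H7A library, lists that came within the random range were, among exonic classes, histones (66.7%), ribosomal proteins (50.0%), hnRNP and SR (63.6%) and cell cycle (62.9%), and with at least 50 reads ribosomal (33.3%) and mitochondrial ribosomal proteins (57.1%). Lists that left it were ZNF (50.8% with at least 50 reads, 62.0% among exonic classes), translation factors (60%, 69.0%) and the respiratory chain (66.7% among exonic classes). In the ZC3H7B library histones (60%, exonic) and the respiratory chain (33.3%, at least 50 reads) came within it and ribosomal proteins (50.0%, exonic) left it.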

Other observations

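The genes outside the naming rule in this part, and the tests with distinct reads, with matching on the 3' UTR share and on mitochondrially encoded genes, were chosen after their results were seen, and the tests within genes with at least 5 clusters and in bins of distinct reads after the pattern was seen. A few transcripts carried many clusters upstream of the coding sequence or in introns, often in both libraries. C6orf62 had 12 clusters in its 5' UTR in each library, of 26 and 31 in all. ZC3H11A, which encodes another CCCH zinc finger protein, had 10 of 21 in the ZC3H7A library and 18 of 40 in the ZC3H7B library, and the transcription factor gene JUN had 7 of 15 and 1 of 10. Intronic clusters were most numerous on C16orf72, with 62 of 81 and 75 of 98. MRPL19 had 38 of 61 and 29 of 53, MBD3, which encodes a methyl-CpG binding domain protein, 25 of 39 and 37 of 42, and ZNF536 16 of 18 and 50 of 59. Of the 50 genes with the most intronic clusters in each library 27 were shared, and of the 50 with the most 5' UTR clusters 17 were shared, where independent lists from all listed genes would share 0.246. Sharing was no feature of these regions alone, with 23 shared for coding sequence and 20 for 3' UTRs, and across genes the rank correlation of cluster numbers was lowest for 5' UTRs (Spearman's rho 0.285).

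ZNF zinc finger genes carried clusters more often than coding genes at large. Of 518 annotated coding ZNF genes, 314 (60.6%, 56.3 to 64.9%) were listed for ZC3H7A and 316 (61.0%, 56.7 to 65.2%) for ZC3H7B, against 37.8% and 42.0% of all coding genes. Cytosolic ribosomal protein genes were listed for 73 and 69 of 87. Expression was not analysed here. The reads of ERC1 were concentrated in few of its clusters. In the ZC3H7B library its 105 clusters, 54 of them intronic, held 281 reads on average and 10 at the median, and this 28.1-fold ratio was the highest of 1631 genes with at least 20 clusters. ARGLU1 followed at 15.7-fold, and the median of these genes was 1.54-fold. In the ZC3H7A library ERC1 was also the highest, at 4.76-fold, of 521 genes. In distinct reads these ratios were lower, at 9.60-fold for ERC1 and 6.31-fold for ARGLU1 in the ZC3H7B library and 3.04-fold for ERC1 in the ZC3H7A library.

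The ZC3H7A library had a smaller share of clusters in 3' UTRs and a larger share in coding sequence and 5' UTRs than the ZC3H7B library. Different genes with clusters do not account for all of this, since the mean difference of the 3' UTR share within genes with at least 5 clusters in both libraries was 13.3 percentage points (12.7 to 13.9, over 3175 genes), above 4.01 points, which is 0.25 of the pooled difference. Fewer distinct reads per gene in the ZC3H7A library go with part of it and do not account for all of it, since the 3' UTR share was higher at more distinct reads in both libraries, yet the ZC3H7B share lay above with separate intervals in 5 of 5 bins, from 35.9% against 30.6% in the lowest to 58.7% against 45.1% in the highest (16.1 points when pooled). A difference between the proteins in the region bound may underlie the pattern, as a hypothesis, and so may any difference between single libraries, such as in RNase digestion or crosslinking. Library and protein cannot be told apart with 1 library each.

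The ZC3H7A library also had more reads on 7 housekeeping lists (histones, cytosolic and mitochondrial ribosomal proteins, proteasome, respiratory chain, cytoskeleton with glycolysis, chaperones), of which 4 stayed below the 2.5th percentile by mean reads per cluster, with smaller medians (histones -1.29, cytosolic ribosomal proteins -0.58, respiratory chain -0.48, proteasome -0.46). PCR duplication in the ZC3H7A library does not account for all of it, since 7 of 7 lists stayed below that percentile with distinct reads. Medians then ran from -0.84 (chaperones) to -2.65 (histones), against -1.02 and -3.05 with reads, so a part is not excluded. Fewer 3' UTR clusters were tested list by list against random lists matched on the 3' UTR share. They do not account for all of the difference in the histone, both ribosomal protein and respiratory chain lists (each at the 0th percentile). The same holds for the cytoskeleton list (0.285th). They stay open for the proteasome (3.45th) and chaperone lists (13.1th). A part is not excluded for any list, since matching moved the random range towards the ZC3H7A library. For histones this range was -0.75 to 0.62 before and -1.41 to 0.04 after matching. Background from abundant RNA could not be judged from mitochondrially encoded genes, because 0 entries for them were listed in either table and it is unknown whether the annotation held them. The higher shares of tRNA (17.8-fold) and other small structured RNA entries (13.3-fold, in distinct reads) in the same library go with such background without deciding it. There was no control library, so this explanation stays open. The protein, and how many clusters were called in each library, also stay open.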
